A study of Arabidopsis thaliana with 9 samples.

How the data were processed

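RNA from whole Arabidopsis thaliana roots was measured on the Affymetrix AraGene 1.0 ST array, a platform with several probes along each transcript. The deposited table held log2 values for 38408 probe sets on 9 arrays, 3 in each of 3 groups. Per the submitters' processing notes, the deposited log2 values were made by the authors with RMA in the oligo package, and limma, R 4.0.0 and TAIR10 were also named there. RMA as usually run corrects the background, applies quantile normalization and summarises the probes of each set, so a change shared by most transcripts would be removed from these values. The array medians lay between 3.27 and 3.35, the highest value of each array between 13.92 and 14.00, and no pair of arrays held identical values. Detection calls, slides and scan dates were not used here, so signal over background was not known for any probe set. Effects of slide or scan date were not assessed. The stated precision covers only the spread between the arrays of a group, which came from a single tube.

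Probe sets were named through the platform annotation, with symbols updated by gene identifier from a RefSeq gene table of assembly TAIR10.1, of which no coordinates were used. Of the 38408 probe sets, 16722 were paired with exactly 1 gene, 759 with several and 20927 were unnamed here. Of those with 1 gene, 16574 were matched in the RefSeq table and 148 kept the platform symbol. No gene is named from a probe set with several. A locus identifier stands for a gene without a symbol. Among the 154 genes with more than 1 probe set, calls differed between the probe sets for 14 genes in the first-actuated and ground comparison, 6 in the last-actuated and ground comparison and 15 between the in-flight groups, and 0 genes were called in opposite directions.

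The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 17481 probe sets paired with at least 1 gene. All 9 arrays entered the fit, so the 3 groups shared an estimate of the residual spread, and no batch term was included. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called, and fold changes are stated on the log2 scale with limma's standard error. A moderated F test covered any difference among the 3 groups. All adjusted p-values below come from limma. On simulated data for the first-actuated and ground comparison, with the spread of the 17481 probe sets and 200 changed genes, 22 of 50 changes of 0.5 on the log2 scale were recovered, 49 of 50 of 1, 49 of 50 of 1.5 and 50 of 50 of 2. Of 183 calls in all, 10 were false and 3 were members of a simulated list shifted together. That list of 20 genes, shifted by 0.4, had a camera p of 5.3e-24, and 3 of 200 unchanged lists had an unadjusted p under 0.05. The simulated genes varied independently of each other, so these list values do not carry over to lists of correlated genes. In the measured heat shock and chloroplast-encoded lists below, the estimated correlations were 0.42 and 0.45.

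Gene lists and tissue markers were fixed before the data were examined. A list member was matched by locus and dropped where the RefSeq symbols did not hold its symbol and no other locus did. Of 474 members listed by name, which leaves out the lists of chloroplast-encoded and mitochondria-encoded genes, 55 had a named probe set. Those lists had 63 and 0 measured genes. Of 29 lists, 7 had at least 3 measured members and were tested: early touch and calcium genes, auxin response, abscisic acid and cold, the unfolded protein response, cell wall expansion, defence and chloroplast-encoded genes. Because few members were named, 28 further lists were drawn from the platform's gene names before any test, of which 27 were tested. They hold loci of heat shock, hypoxia and rapid wound and touch responses, and gene families. A further 3 lists, of sugar-repressed genes, branched-chain amino acid breakdown and nuclear photosynthesis genes, were chosen after the largest changes had been seen, and the genes that prompted them were left out. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional p tests whether the genes of a list move, on balance, one way and whose mixed p tests whether they change in either direction. Neither compares a list with other genes. The adjustment ran over the 7, 27 and 3 lists separately within each comparison. Each locus was represented by its probe set of highest mean over the 9 arrays.

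Named genes followed a rule fixed before the data were examined. It took, per comparison, the 12 largest increases and the 12 largest decreases among called probe sets with 1 gene whose groups did not overlap. It also took up to 4 members of smallest p in each list described, and the 5 largest mean changes per direction among probe sets called in both in-flight groups. GRF8, the 14-3-3 kappa gene carried by the transgene, was also to be named, but it had no named probe set and was not analysed here. Only some of the genes selected are described.

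Alternatives covered renewed quantile normalization, median centring, cyclic loess, filters on dim probe sets, the inclusion of unnamed probe sets, probe sets with exactly 1 gene, other variance models, array weights, fits of only the compared groups, the replicate number as a block, stricter thresholds and leaving out each array. Tables and figures were made with Python 3.11.15 and matplotlib 3.10.9.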

Results

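Roots of 10-day-old seedlings were compared between the ground and a parabolic flight of an F-104 jet. The seedlings, in the Wassilewskija background, overexpressed the 14-3-3 kappa protein fused to GFP. They were held in Kennedy Space Center fixation tubes, sealed devices that release RNAlater onto the plants when actuated. The ground tube was actuated during the flight. In-flight tubes were carried in flight suit pockets, and the ground tube was held by a person. By the labels' protocol, the first in-flight tube was actuated during low-altitude acceleration, and the last after the parabola, which followed a climb at 4 g for about 30 s and included about 10 s of microgravity. The series' design text places the in-flight actuation some 1.5 min into regained level flight without separating the tubes, so the timing of the first tube rests on the protocol. Each group held 3 arrays from roots of a single tube. The p-values therefore measure the spread between root pools of a tube, and tube and condition cannot be told apart.

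The 3 groups separated on the first pair of principal components. The first component held 33.5% of the variance and set the first-actuated arrays, at 21.55 to 23.79, apart from the others, at -16.45 to -7.31. Ground and last-actuated arrays parted on the next component, with 19.1% of the variance. Pairs of arrays correlated at 0.98 to 0.9895 over all probe sets. Across the 3 groups, 1337 of 17481 named probe sets differed by the moderated F test.

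**Figure D1:**
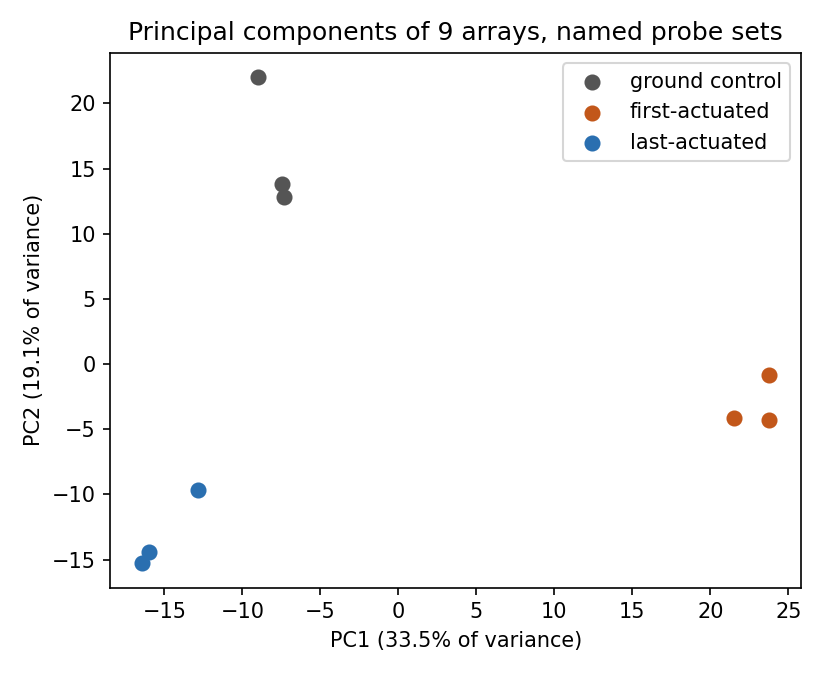
Principal component scores of the 9 arrays over the named probe sets, with PC1 (33.5% of variance) on the horizontal and PC2 (19.1%) on the vertical axis and a point per array, coloured by group. The first-actuated arrays sit at 21.55 or above on PC1 and all others at -7.31 or below.

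By the protocol's timing, the comparison of first-actuated and ground roots addresses the state of the roots early in the flight. AT1G26730, an EXS family gene, rose by 2.60 ± 0.26 (SE) on the log2 scale, a 6.07-fold increase (adjusted p = 0.000574), and AT5G53680, an RNA-binding protein gene, rose by 2.56 ± 0.23. AT3G02480, a late embryogenesis abundant protein gene, rose by 1.74 ± 0.24, and the DnaJ-domain gene AT1G71000 by 1.70 ± 0.12. Class III peroxidase AT1G49570 fell by 2.31 ± 0.15, to 0.202 of its ground level, and the sugar transporter gene AT3G05150 fell by 2.27 ± 0.10, to 0.208 of it (adjusted p = 1.28e-05). GH3.3, which encodes an enzyme that conjugates auxin to amino acids, fell by 1.73 ± 0.22, and SWEET2, a sugar transporter gene, fell by 1.59 ± 0.32. In all, 394 probe sets rose and 461 fell. Of these, 96 rose and 79 fell by at least 2-fold. The arrays of the groups did not overlap in any of the 855, and did not overlap in 20.4% of all probe sets, where chance gives 10%.

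Among 9 auxin response genes measured, 0 rose and 3 fell in the first-actuated roots, against 1 up and 4 down when adjusted over the list alone. Those that fell were GH3.3, WES1 (-0.59 ± 0.13), also a GH3 enzyme gene, and LBD29 (-0.82 ± 0.18), a transcription factor gene of lateral root formation. The list as a whole did not pass camera (adjusted p = 0.082) but passed fry downward (adjusted p = 0.0062). Outside that list GH3.17, another GH3 family gene, rose by 0.90 ± 0.11 (adjusted p = 0.0015). The Aux/IAA and GH3 family had 1 up and 2 down of 14 (camera adjusted p = 0.97). KIN1, a cold and abscisic acid responsive gene, rose by 1.52 ± 0.12 and was alone among 5 such genes in passing, with 2 up when adjusted over the list alone (list adjusted p = 0.082 by camera and 0.022 upward by fry). In the wall expansion list XTH19, a xyloglucan-modifying enzyme gene, rose by 0.76 ± 0.16, and the other 5 members did not pass, with 2 up when adjusted over the list alone (list adjusted p = 0.059 by camera and 0.0062 upward by fry). The XTH19 probe set was dim, at 2.41 on the ground and 3.17 in first-actuated roots, below the array medians. The defence list had calls both ways among 5 members measured, PUB24 and EXO. The ubiquitin ligase gene PUB24 rose by 1.04 ± 0.13 while EXO, a brassinosteroid-responsive cell surface protein gene, fell by 1.26 ± 0.17, the same counts when adjusted over the list alone (list adjusted p = 0.42). None of 6 early touch and calcium genes and none of 4 unfolded protein response genes was called by limma, against 3 and 1 up when adjusted over the list alone and 3 and 2 at an unadjusted p under 0.05 (list adjusted p = 0.128 and 0.296).

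Of 21 heat shock loci measured, 5 rose and 0 fell in first-actuated roots, with a median change of 0.26 on the log2 scale (camera adjusted p = 2e-05). With an estimated correlation the adjusted p = 0.67, and the list passed fry upward (adjusted p = 0.022). Adjusted over the list alone, 10 rose and 1 fell. On the ground arrays these loci were already bright, at a median log2 of 9.86. Besides AT1G71000, those with the smallest p were AT3G07150 (1.02 ± 0.12), AT5G37670, a small heat shock protein gene (0.64 ± 0.09), and ATHSP22.0, a small heat shock protein gene of the endomembrane system (0.51 ± 0.08). Rapid wound and touch loci had 5 up and 2 down of 25, with a median of 0.21 (camera adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation). AT4G29780 rose by 1.26 ± 0.12, whereas AT1G76600 fell by 1.14 ± 0.09. The ATG8 family, which encodes ubiquitin-like proteins of autophagosomes, had 2 of 9 members down and 0 up, with a median of -0.29 (camera adjusted p = 0.0009, and adjusted p = 0.57 with an estimated correlation). ATG8E fell by 0.64 ± 0.12 and ATG8H fell by 0.69 ± 0.15. None of 63 chloroplast-encoded genes was called by limma, also when adjusted over the list alone, and 10 had an unadjusted p under 0.05, although the list passed camera upward with a median of 0.10 (adjusted p = 0.0016, and adjusted p = 0.48 with an estimated correlation). The count of called probe sets was 512 when only the compared groups were fitted, 549 without ground replicate 1 and 557 without ground replicate 2.

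Last-actuated roots, fixed after the climb and the parabola, were set against the same ground arrays. AT5G53680 rose by 2.87 ± 0.23 (7.30-fold, adjusted p = 0.000198) and AT1G52870, a peroxisomal membrane family gene, by 2.19 ± 0.12 (4.57-fold). AT3G17400, an F-box gene, rose by 2.29 ± 0.13, the deaminase gene AT3G48540 by 1.91 ± 0.15, AT1G50110, a branched-chain aminotransferase gene, by 1.86 ± 0.14, and AT2G43560, a peptidyl-prolyl isomerase gene, by 1.71 ± 0.14. The AT3G17400 probe set was dim on the ground, at 2.90, below the array medians. GH3.3 fell by 2.61 ± 0.22, to 0.164 of its ground level. The lipase gene DLAH fell by 1.88 ± 0.26. Lower too were AT2G36690, an oxygenase gene (-1.85 ± 0.20), and AT1G72920, of the TIR-NBS class of immune receptors (-1.77 ± 0.24). A total of 162 probe sets rose and 154 fell, of which 46 and 22 changed by at least 2-fold. The arrays did not overlap in any of the 316, and did not overlap in 16.6% of all probe sets, against 10% by chance.

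Among the 21 heat shock loci, 8 rose and 0 fell, with a median of 0.37 (camera adjusted p = 3.4e-18). With an estimated correlation the adjusted p = 0.47, and the list passed fry upward (adjusted p = 0.0045). Adjusted over the list alone, 16 rose and 0 fell. AT1G71000 rose by 1.71 ± 0.12, AT3G07150 by 1.33 ± 0.12, ATHSP22.0 by 0.98 ± 0.08 and AT5G37670 by 0.81 ± 0.09. Of 4 unfolded protein response genes, 2 rose and 0 fell, also when adjusted over the list alone. They were BIP1 (0.71 ± 0.13), a chaperone gene of the endoplasmic reticulum, and ATERDJ3B (0.68 ± 0.13), the gene of a DnaJ partner. The BIP1 probe set was dim, at 2.65 on the ground, below the array medians, and 3.36 in last-actuated roots. That list passed camera (adjusted p = 0.0057, and adjusted p = 0.29 with an estimated correlation). KIN1 rose by 0.88 ± 0.12, the sole call among the 5 cold and abscisic acid genes, also when adjusted over the list alone (list adjusted p = 0.054). GH3.3 was the sole auxin response gene called, against 1 up and 3 down when adjusted over the list alone (list adjusted p = 0.22 by camera and 0.022 downward by fry). In the defence list PUB24 fell by 0.83 ± 0.13 and the other 4 members did not pass, also when adjusted over the list alone (list adjusted p = 0.22). None of the early touch and calcium or the wall expansion genes was called by limma, in either adjustment, with 1 of each list at an unadjusted p under 0.05 (list adjusted p = 0.646 for each). The wall expansion list had a median of -0.12 and a mean of 0.02.

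Of 25 rapid wound and touch loci, 0 rose in last-actuated roots and 3 fell, with a median of -0.18 (camera adjusted p = 0.0032, and adjusted p = 0.52 with an estimated correlation). AT4G27654 fell by 1.51 ± 0.15, AT4G29780 fell by 0.71 ± 0.12 and AT1G76600 fell by 0.56 ± 0.09. Chloroplast-encoded genes again had 0 calls by limma in either adjustment and 8 at an unadjusted p under 0.05, with a median of 0.09 (camera adjusted p = 0.0057, and adjusted p = 0.65 with an estimated correlation). The count of called probe sets was 202 without ground replicate 2, 179 without last-actuated replicate 2 and 182 without last-actuated replicate 3.

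**Figure D2:**
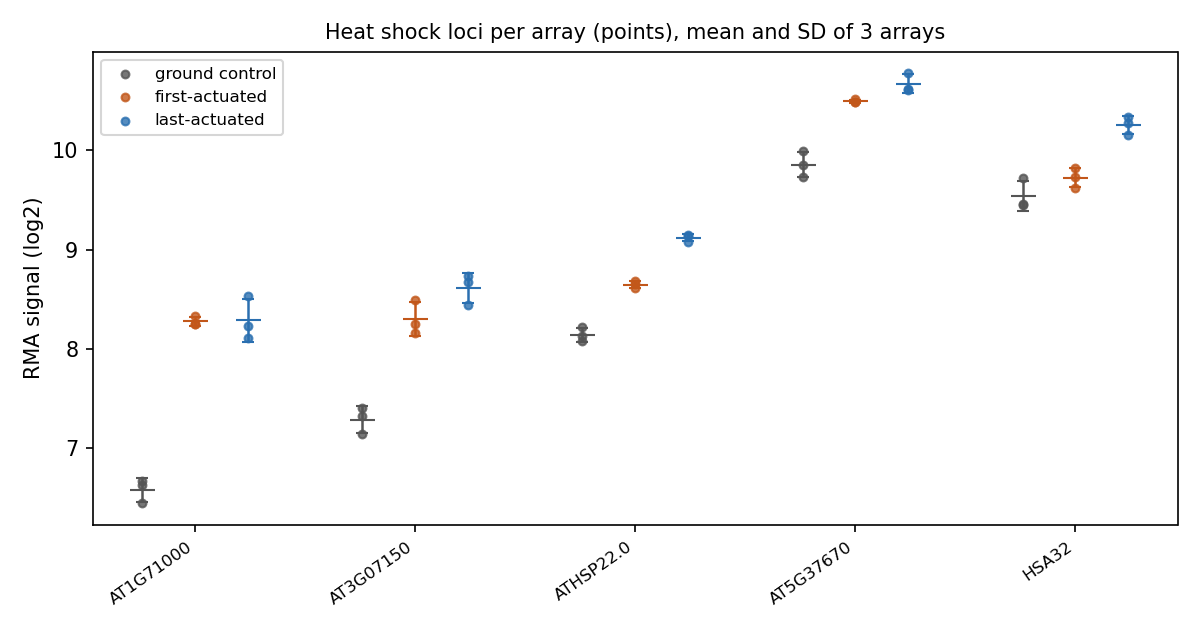
RMA signal (log2) of 5 heat shock loci named in the text, with a point per array, the bar at the mean and the whiskers at 1 SD of 3 arrays, by group. AT1G71000 rose from 6.58 on the ground to 8.28 in first-actuated and 8.29 in last-actuated roots.

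Of the probe sets called in both comparisons with ground, 76 rose in both in-flight groups and 44 fell in both, while 9 rose in first-actuated and fell in last-actuated roots and 11 did the reverse. Those called in the same direction numbered 120, and 77 without last-actuated replicate 2. Independent lists as long as those of the calls in each comparison would share 3.65 up and 4.06 down. In 100 simulations of unchanged groups against shared controls, 0 probe sets were called in the same direction in both. With no changed gene simulated, few calls could arise in either comparison, so this 0 is not a chance level for the 120. The ground arrays were not split between the 2 comparisons, so part of the excess over independent lists may come from the shared controls. The largest mean increases were those of AT5G53680, AT1G52870, AT1G26240, an extensin-like gene, AT1G02700 and AT1G71000, and the largest mean decreases those of GH3.3, AT1G72920, AT1G13670, AT2G36295 and AT5G18475. AT1G26240 on the ground (2.80) and AT2G36295 in first-actuated (2.94) and last-actuated roots (2.49) were dim, below the array medians. Across probe sets, which are not independent replicates, the log2 changes correlated at 0.32, against 0.5 in the simulations, with a covariance of 0.0205 against 0.0094. Their signs matched for 63.7% of probe sets, against 66.7% in the simulations.

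The in-flight groups were also compared with each other, as by the labels' protocol they were fixed at different stages of the flight. AT3G05150 was higher in last-actuated roots by 2.72 ± 0.10 (6.61-fold, adjusted p = 2.03e-06) and AT1G49570 by 2.59 ± 0.15. So were the lectin gene AT5G35940 (2.45 ± 0.28), BGLU28, a beta-glucosidase gene (2.37 ± 0.25), the defensin-like gene LCR35 (2.26 ± 0.24) and AT1G56680, a chitinase gene (2.00 ± 0.20). AT3G01260, of the galactose mutarotase family, was lower, by log2 -2.90 ± 0.25, AT3G02480 by -2.74 ± 0.24, DLAH by -2.16 ± 0.26 and LHB1B2, a light-harvesting protein gene, by -1.96 ± 0.28. In total 626 probe sets were higher and 551 lower in the last-actuated roots, of which 113 and 119 changed by at least 2-fold. These were the most calls of the 3 comparisons. Without last-actuated replicate 3 the order turned, with 724 between the in-flight groups and 774 for first-actuated against ground. The arrays did not overlap in any of the 1177, and did not overlap in 21.8% of all probe sets, against 10% by chance.

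Rapid wound and touch loci had 2 members higher and 9 lower in last-actuated than in first-actuated roots, with a median of -0.27 (camera adjusted p = 0.00023, and adjusted p = 0.66 with an estimated correlation). AT4G27654 differed by -2.13 ± 0.15, AT4G29780 by -1.97 ± 0.12, AT4G27652 by -1.03 ± 0.13 and AT4G27657 by -0.97 ± 0.13. Heat shock loci had 2 of 21 higher and 0 lower, ATHSP22.0 (0.47 ± 0.08) and HSA32 (0.53 ± 0.10), with a median of 0.17 (camera adjusted p = 0.00045, and adjusted p = 0.84 with an estimated correlation). ATG8E (0.88 ± 0.12) and ATG8H (0.83 ± 0.15) were higher, the calls among 9 ATG8 genes (camera adjusted p = 0.013, and adjusted p = 0.66 with an estimated correlation). Of 7 WRKY transcription factor genes, WRKY29 (1.38 ± 0.13) and WRKY6 (0.46 ± 0.10) were higher and 0 were lower. That list had an adjusted p = 0.038, and adjusted p = 0.66 with an estimated correlation.

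Of the lists fixed beforehand, 0 of 7 passed camera between the in-flight groups. HAT2, an auxin-responsive homeodomain gene, was higher by 1.01 ± 0.13 and GH3.3 lower (-0.88 ± 0.22), the sole calls of 9 auxin response genes, also when adjusted over the list alone (list adjusted p = 0.996). The camera direction of that list was up, with a median of -0.01 and a mean of -0.04. PUB24 was lower (-1.88 ± 0.13) and EXO higher (0.88 ± 0.17) among 5 members of the defence list, with 2 up and 1 down when adjusted over the list alone. The median of that list was 0.14, its mean -0.08 and its list adjusted p = 0.64. XTH19 was lower (-1.10 ± 0.16) among 6 wall expansion genes, with 1 up and 4 down when adjusted over the list alone (list adjusted p = 0.083 by camera and 0.0043 downward by fry). Its means, 3.17 in first-actuated and 2.07 in last-actuated roots, lay below the array medians, so the size of this change is uncertain. CML37, a calmodulin-like gene, was lower (-0.52 ± 0.09) among 6 touch genes, with 2 down when adjusted over the list alone (list adjusted p = 0.31). KIN1 was lower (-0.63 ± 0.12) among 5 cold and abscisic acid genes, whose median was 0.06 and mean -0.11 (list adjusted p = 0.64). ATERDJ3B was higher (0.90 ± 0.13) among 4 unfolded protein response genes (list adjusted p = 0.33). Each of those was also the sole call when adjusted over the list alone. Chloroplast-encoded genes had 0 calls by limma in either adjustment and 4 at an unadjusted p under 0.05 (list adjusted p = 0.64). The count of called probe sets was 724 without last-actuated replicate 3 and 1794, of which 938 were unnamed, over all 38408 probe sets.

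**Figure D3:**
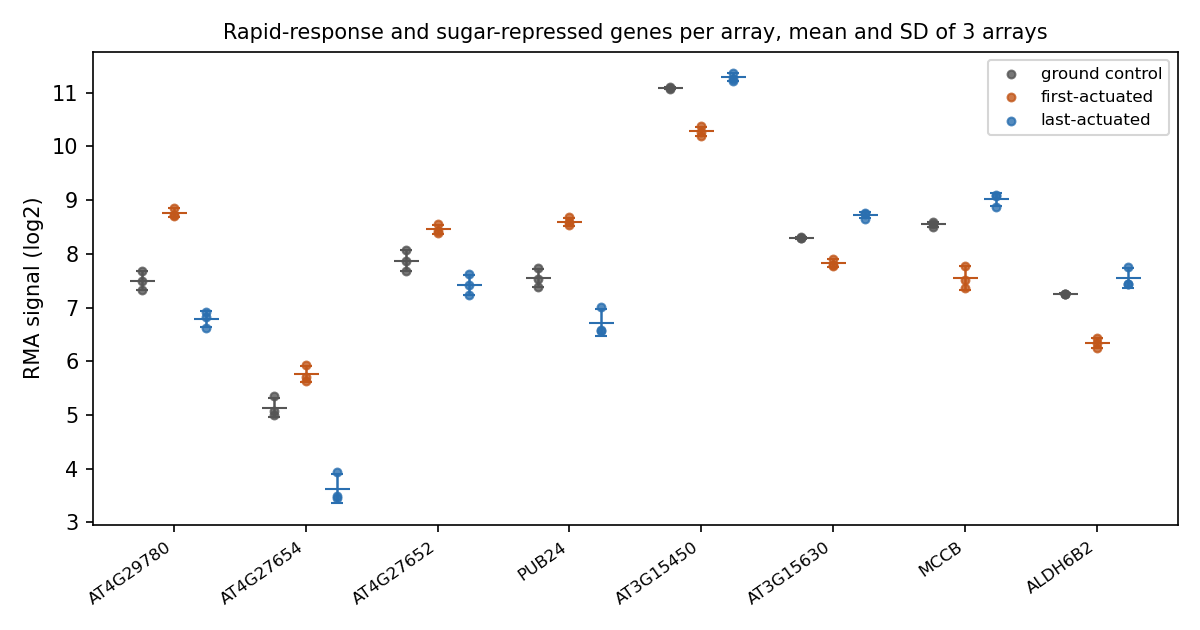
RMA signal (log2) of 4 genes of the rapid response and defence lists and 4 of the lists of sugar-repressed and branched-chain breakdown genes, with a point per array, the bar at the mean and the whiskers at 1 SD of 3 arrays, by group. In AT4G29780 the first-actuated arrays lie highest (mean 8.76) and the last-actuated lowest (mean 6.79), and in MCCB the order is turned (7.55 and 9.01).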

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

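Of the tests below, those on shoot tissue and on a single first-actuated array behind the separation of that group, and the lists of sugar-repressed and branched-chain breakdown genes, were chosen only after the result was seen. Some genes moved in opposite directions in the 2 in-flight groups against ground, with the difference itself called by limma. Counting all such probe sets, 9 rose in first-actuated and fell in last-actuated roots, and 11 did the reverse. Among named genes, the change from first-actuated to last-actuated roots was -1.97 for AT4G29780, -2.13 for AT4G27654, -1.88 for PUB24, 2.26 for LCR35 and 0.90 for AT3G15630, on the log2 scale. The LCR35 probe set was dim in first-actuated roots, at 2.50, below the array medians. The rapid wound and touch loci as a list differed likewise (camera adjusted p = 0.00023, and adjusted p = 0.66 with an estimated correlation).

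Signal also differed in probe sets that the comparisons left out. Among the 20927 unnamed probe sets, 666 were called between first-actuated and ground arrays, 248 between last-actuated and ground arrays and 938 between the in-flight groups, in a fit of all probe sets. That fit gave 1211, 442 and 1794 calls in all, so it called fewer named probe sets than the main fit.

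The first-actuated arrays stood apart from the other groups. A single deviating array was argued against by the calls between the in-flight groups, made anew without each first-actuated array in turn, which numbered 855 or more against 1177 with all arrays. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. The real split gave 855, 316 and 1177 calls for first-actuated against ground, last-actuated against ground and the in-flight groups, and the highest other split gave 0 in each (1 split of the 10 reached the real count). Of 100 splits of the 9 arrays into 3 groups, only the real one (1) reached its 1337 calls of the F test and the highest other gave 501. A random division of the arrays was thus argued against for that count. As the arrays of a group share a tube, any difference between tubes would give the same result. Whether the stage of flight or the tube and its handling may set the first-actuated arrays apart stays open.

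Of 21 heat shock loci, 5 rose in first-actuated and 8 in last-actuated roots, and the list's camera calls were lost with an estimated correlation (adjusted p = 0.67 and 0.47). Fry, which does not compare the list with other genes, called it upward in both (adjusted p = 0.022 and 0.0045). On the ground arrays the loci had a median log2 of 9.86, with 15 of the 21 in the top 5% of named probe sets. Most of them therefore did not start from a low level. A single ground array was argued against, since the median change in last-actuated roots kept at least 0.975 of its size without any 1 of them. A movement of all bright probe sets was also argued against, as the medians of 0.37 in last-actuated and 0.26 in first-actuated roots lay at percentile 100 of 10000 random lists matched on mean level, whose medians centred on 0.025 and 0.0047. Warmth or handling in the flight suit may have differed from the ground tube, which these data cannot separate from the flight itself.

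Genes repressed by sugar and genes of branched-chain amino acid breakdown had 4 of 8 and 4 of 6 members down in first-actuated roots against ground. Of these 14 genes, 10 were called higher and 1 lower in last-actuated than in first-actuated roots, with a median change of 0.766. A single first-actuated array was argued against, since that median kept at least 0.955 of its size without any 1 of them. A different amount of shoot tissue predicted photosynthesis genes called in a single direction, with a median that is a sizeable part of 0.766. The 19 nuclear photosynthesis genes, LHB1B2 included, had a median of -0.0825 with a bootstrap error of 0.0601, which fell short of that. They had 1 call up and 2 down. Without LHB1B2, which prompted the list, the other 18 had 1 up and 1 down. Calls both ways also missed the prediction set for no such difference, so shoot tissue stays open. A difference in carbon supply between the tubes may be considered only as a hypothesis, as no test here could tell it from other differences between the tubes.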

How the results depend on the processing

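The alternative over probe sets with exactly 1 gene was chosen after seeing the data. Of 114 alternative counts of called probe sets, 95 stayed within 1.5 times the stated count. At adjusted p under 0.01 the counts were 335 for first-actuated against ground, 137 for last-actuated against ground, 502 between the in-flight groups, 575 for any difference and 51 called in the same direction in both comparisons with ground. Requiring at least a 2-fold change gave 175, 68, 232, 224 and 20 in that order. These follow from the stricter criteria. With only the 2 groups compared, first-actuated against ground gave 512 calls, with fewer arrays behind the spread. Over all probe sets, unnamed included, the 3 comparisons gave 1211, 442 and 1794 calls, as more probe sets were tested. Of these, 666, 248 and 938 were unnamed, so fewer named probe sets were called than in the main fit. Leaving out 1 array gave 549 to 807 calls for first-actuated against ground, 179 to 333 for last-actuated against ground, 724 to 1119 between the in-flight groups, 919 to 1213 for any difference and 77 to 99 in the same direction in both. The lowest came without ground replicate 1, last-actuated replicate 2, last-actuated replicate 3, first-actuated replicate 3 and last-actuated replicate 2 respectively. A similar count need not hold the same probe sets. With 1 array left out, 502 to 730 of 855, 167 to 285 of 316 and 686 to 1063 of 1177 main calls were kept. Fits of only the 2 groups compared kept 498, 194 and 823 of them.

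The replicate numbers shared by the groups did not pair the arrays, since residuals of same-numbered arrays correlated at -0.119 to 0.057 and 0 of 9 arrays correlated best with their own number. With the replicate number as a block the counts were 723, 247, 1035, 1105 and 105. For the 203 named gene results called, 353 of 3451 alternatives lost the call, 273 of them with an array left out. The sign changed in 0, but the groups did not overlap in any called probe set. Leaving out an array or changing the variance model could therefore not turn a sign, so this 0 says little. Of 240 alternatives for 40 list results, 32 lost the call, 8 gained it and 0 reversed. Apart from the lists fixed beforehand, only results that had passed camera entered here, so gains elsewhere were not counted. Of the 27 lists drawn from the platform's gene names, fry called 5, 2 and 8 in the 3 comparisons, where camera called 4, 5 and 4. Of the 32, 20 lost it with an estimated correlation and 9 with fry, which also gave 5 of the 8 gains. The losses with fry included chloroplast-encoded genes (adjusted p = 0.20 and 0.35) and rapid wound and touch loci (0.13 and 0.093) in first-actuated and last-actuated roots against ground, and heat shock loci between the in-flight groups (0.051). Chloroplast-encoded genes in last-actuated roots lost it when quantile normalization was repeated (adjusted p = 0.134), and WRKY genes between the in-flight groups with that (0.0842) or without the dimmest probe sets (0.0975). The cause was not tested. Without ground replicate 2, 557 and 202 calls were made for the in-flight groups against ground in turn, and without last-actuated replicate 3, 182 for last-actuated against ground. Signal over background was not known, so the limit for dim probe sets could not be set.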

Other observations

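In this part, the tests of sugar-repressed, branched-chain breakdown and photosynthesis genes were chosen only after the largest changes had been seen, so they are not independent of that reading. Branched-chain amino acid breakdown genes had 4 of 6 members down and 0 up in first-actuated roots against ground, with a median of -0.73 (camera adjusted p = 8.7e-07, and adjusted p = 0.052 with an estimated correlation). AT1G21400, a branched-chain keto acid dehydrogenase subunit gene, fell by 1.25 ± 0.14, MCCB, a methylcrotonyl-CoA carboxylase subunit gene, by 1.00 ± 0.12, and ALDH6B2, an aldehyde dehydrogenase gene of valine breakdown, by 0.92 ± 0.11. In last-actuated roots 0 of the 6 were called by limma against ground and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.64), and 3 were higher than in first-actuated roots (camera adjusted p = 1.6e-05, and adjusted p = 0.047 with an estimated correlation). Of 8 sugar-repressed genes, 1 rose and 4 fell in first-actuated roots (camera adjusted p = 5.4e-05, and adjusted p = 0.063 with an estimated correlation). AT3G15450 fell by 0.81 ± 0.08 and AKINBETA1, a subunit gene of the SnRK1 kinase, by 0.66 ± 0.10, while AT1G56220 rose by 0.50 ± 0.09. Between the in-flight groups, 7 of the 8 were higher and 1 lower in last-actuated roots (camera adjusted p = 1.2e-06, and adjusted p = 0.047 with an estimated correlation). Against ground, 1 of the 8 rose in last-actuated roots (camera adjusted p = 0.021, and adjusted p = 0.23 with an estimated correlation).

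Among 18 nuclear photosynthesis genes, with LHB1B2 left out because it prompted the list, 0 rose and 2 fell in first-actuated roots (camera adjusted p = 0.28). In last-actuated roots 0 rose and 1 fell against ground, LHCB4.1 (-0.47), with a list adjusted p = 0.021, and adjusted p = 0.15 with an estimated correlation. Between the in-flight groups PSAN was higher by 0.76 and PSBW lower (-0.71).

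Hypoxia loci showed no common direction. Of 14, 1 rose and 1 fell in each in-flight group against ground. AT3G23170 rose by 1.03 ± 0.09 in first-actuated and 0.85 ± 0.09 in last-actuated roots, and AT5G66985 fell by 0.92 ± 0.15 and 0.87 ± 0.15. The list did not pass camera in any comparison (adjusted p = 0.98, 0.91 and 0.93), and in last-actuated roots its median was -0.05 and its mean 0.03. Of the gene families tested against ground, glycosyltransferases passed camera in last-actuated roots with 0 up and 2 down of 51, UGT73B3 (-1.12 ± 0.16) and UGT72E1 (-0.86 ± 0.17), with an adjusted p = 0.031, and adjusted p = 0.47 with an estimated correlation. So did the Aux/IAA and GH3 family, in which GH3.3 was the sole call of 14 members and 4 were down at an unadjusted p under 0.05 (adjusted p = 0.031, and adjusted p = 0.47 with an estimated correlation). Expression genes of the plastid genome had 0 of 18 members called by limma in each comparison with ground, with 5 and 6 at an unadjusted p under 0.05 and medians of 0.18 in both (adjusted p = 0.0012 and 0.00016, and adjusted p = 0.67 and 0.52 with an estimated correlation). In each comparison with ground, 0 of the 27 lists drawn from the platform's gene names passed with an estimated correlation, where 4 passed in first-actuated and 5 in last-actuated roots at the preset correlation.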
